A study of Mus musculus with 6 samples.

How the data were processed

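RNA sequencing of prostates from mice with experimental autoimmune prostatitis was available for 6 samples in 2 groups, VUF11207 and DMSO vehicle, with 3 libraries each. Per the labels' protocols, total RNA was extracted with TRIzol and libraries were made with the VAHTS Universal V6 RNA-seq kit. Per the submitters' processing notes, fastp, HISAT2, HTSeq and the mouse build mm10 were used, without versions. The gene annotation, the strand setting and the treatment of reads that match several genes are not given in the sources used here, so values of near-identical genes are uncertain.

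The deposited table holds whole-number read counts per gene symbol, not normalised, for 18697 genes and 6 libraries. Of these libraries, 5 also had a file of their own, and the counts in all 5 files were identical to the table's. Groups came from the sample labels. The column names matched 5 samples with their replicate numbers. The remaining column had the name of a vehicle library that matched no sample's own file, so it entered the vehicle group without a replicate number. By elimination it would be vehicle replicate 1. The labels do not say which mouse each library came from, so p-values measure the spread between these samples. No row lacked a gene name, and 1219 genes had 0 counts in each library.

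Total counts were 20308018 in the unnumbered vehicle library, 33368058 and 25175803 in vehicle replicates 2 and 3, and 29311438, 23915765 and 25979464 in VUF11207 replicates 1, 2 and 3. The 10 most abundant genes of each library took 19.3%, 67.0% and 33.4% of the vehicle counts and 38.7%, 25.9% and 34.0% of the VUF11207 counts, in the same order. In vehicle replicate 2 this left fewer counts for all other genes, and its TMM factor was 0.425.

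Counts were normalised by TMM and filtered with filterByExpr in edgeR 4.0.16, which left 13753 genes. VUF11207 was compared with vehicle by edgeR's quasi-likelihood test with robust dispersion estimates, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Standard errors were derived from the fold change and the F statistic. An exact permutation test of a single value cannot go below 0.1 with 3 libraries against 3, so none is reported. Scaling by library totals alone moved the median log2 fold change of all genes from -0.04 to 0.14.

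Before the data were examined, 52 gene lists (pathways, cell types and neighbouring tissues) were fixed, of 1102 members, 1029 of them found by symbol and 20 by synonym. The 47 lists with at least 5 tested genes were compared by camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01, and again with an estimated correlation and with fry.

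The genes named in the text were set by a rule fixed at the same time. It named 12 genes in advance, then genes past the threshold and, failing those, the 10 with the smallest p among genes with an average log2 CPM of at least 1 and no overlap between the groups, leaving out names of the form Gm with digits, names ending in Rik and LOC identifiers. It also allowed 2 to 4 members of each list that passed, of which the 3 with the smallest p were taken, and up to 2 members the other way. Positions are those of the GENCODE annotation of mm10 (release M21), and the symbols in the table may follow another annotation. A result of 1 gene that the rule names is not reported here. Genes outside the rule are said to have been chosen after their values were seen.

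The test was tried on simulated counts with 50 genes changed at each of 4 fold sizes in each of 5 simulations. Changed genes were drawn from those with an average log2 CPM of at least 1. Each simulated gene varied independently of the others, unlike in these libraries, so recovery in the real data may be lower. With the dispersion of these libraries (13517 genes tested) it recovered 2.80%, 43.2%, 82.4% and 90.8% of genes changed 2-fold, 4-fold, 8-fold and 16-fold, with 40 false calls in all. With a dispersion of 0.02 it recovered 97.6% of those changed 2-fold.

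Alternatives fixed in advance were DESeq2 1.42.0, limma voom with and without sample weights, other scaling and count filters, the replicate number as a block, a minimum fold change and leaving out each library in turn. Alternatives added after seeing the data left out the 2 libraries with most seminal vesicle counts or the 50 most abundant genes, or used the seminal vesicle level or the first principal component as a covariate. Analyses ran in R 4.3.3 and Python 3.11.15.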

Results

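Prostates of mice with experimental autoimmune prostatitis, a model of chronic prostatitis in which an immune response against prostate antigens inflames the gland, were profiled by RNA sequencing. One group had received VUF11207, a small-molecule agonist of the atypical chemokine receptor CXCR7 (gene symbol Ackr3), by daily intraperitoneal injection at 5 mg per kg for 14 days. The other group had received the vehicle DMSO. Each group held 3 libraries. The vehicle libraries were replicates 2 and 3 and a library whose column name matched no sample's own file. That library is called the unnumbered vehicle library, and by elimination it would be replicate 1. Total counts per library ranged from 20308018 in the unnumbered vehicle library to 33368058 in vehicle replicate 2, over 18697 genes. The comparison of VUF11207 with vehicle addresses how activation of CXCR7 bears on injury and fibrosis of the inflamed prostate.

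The specimens differed widely in their content of seminal vesicle, prostate secretory and skeletal muscle transcripts, within both groups. Single genes that show this (Svs5, Svs2, Svs1, Sbp, Pbsn and Myh4) were chosen after their values were seen. Genes of the seminal vesicle list, which encode the secreted proteins of that accessory gland, took 64.4% of all counts in vehicle replicate 2, 16.7% in vehicle replicate 3 and 1.01% in the unnumbered vehicle library. The same genes took 28.4%, 3.92% and 4.95% in VUF11207 replicates 1, 2 and 3. Members of this list did not vary alike. In vehicle replicate 3, Svs2 held 9.95% and Svs5 4.03%, but Svs1 held 0.0245%, less than its 0.0602% in the unnumbered vehicle library. The share of the list thus rests on a few genes and need not rank the libraries as other members do. Svs5, a seminal vesicle secretory protein, held 16.1% of the counts of vehicle replicate 2 and 0.208% of those of the unnumbered vehicle library. Sbp, which encodes spermine-binding protein of the prostatic secretion, held 16.3% in VUF11207 replicate 3 and 0.494% in the unnumbered vehicle library. Pbsn, the androgen-regulated secretory gene probasin, took 2.35% in the unnumbered vehicle library, 0.840% in VUF11207 replicate 2 and at most 0.302% in the other 4 libraries. The Wilson 95% intervals of these shares were at most 0.0175 percentage points wide on either side, and they covered counting error only.

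Myh4, a myosin heavy chain of fast skeletal muscle, was at 665 CPM (normalised read counts scaled to a common library size) in vehicle replicate 3 and 685 in VUF11207 replicate 1, against 0.0740, 3.31, 1.01 and 41.7 in the unnumbered vehicle library, vehicle replicate 2, VUF11207 replicate 2 and VUF11207 replicate 3. For each gene list a level per library was taken, the mean over its genes of log2 CPM minus the mean of the 6 libraries. The skeletal muscle list had levels of 3.66 and 3.74 in vehicle replicate 3 and VUF11207 replicate 1, and of -3.48 in the unnumbered vehicle library. Markers of T cells had levels of 1.08 in the unnumbered vehicle library and 1.01 in VUF11207 replicate 2, against -0.74, 0.10, -0.73 and -0.72 in vehicle replicates 2 and 3 and VUF11207 replicates 1 and 3. Between treatments the seminal vesicle level differed by -0.46 and the skeletal muscle level by 1.15 (VUF11207 minus vehicle). The SD of these levels within groups was 2.80 to 3.75. The seminal vesicle list had 2 of 11 members positive and a median log2 fold change of -2.53. The adjusted p was 0.997 for the seminal vesicle list and 0.0832 for the skeletal muscle list (camera in limma, two-sided). With such a spread these values do not show equal content in both groups. Across genes, libraries of the same group correlated with a median Pearson r of 0.895 over 6 pairs, and libraries of different groups with a median of 0.925 over 9 pairs.

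**Figure D1:**
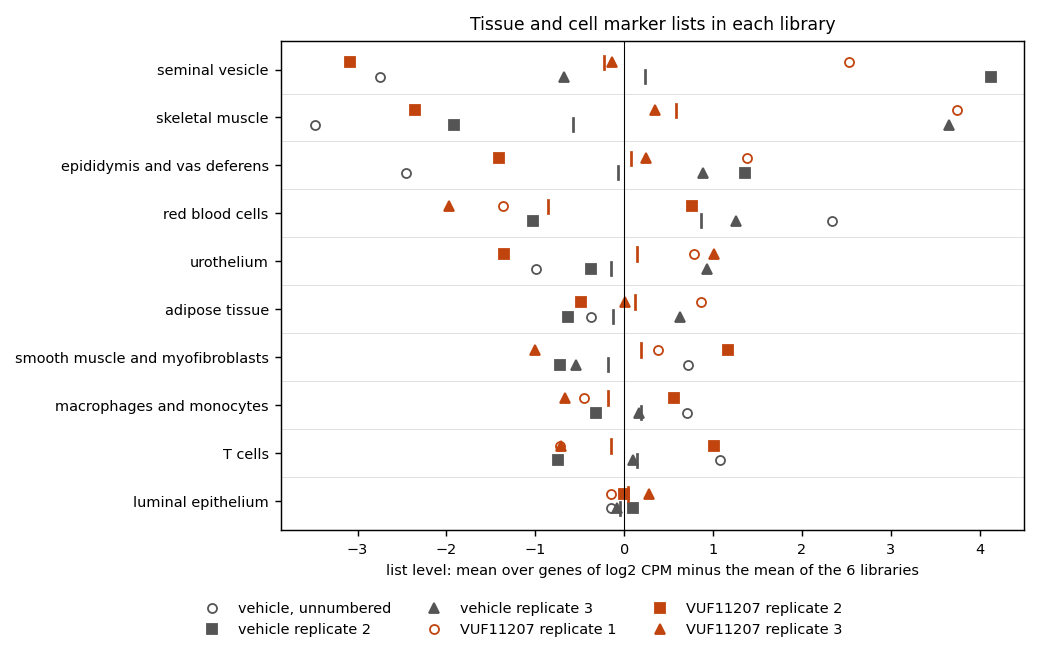
Levels of 10 tissue and cell marker lists in each of the 6 libraries, on a log2 scale (x axis: mean over genes of log2 CPM minus the mean of the 6 libraries). Grey symbols are vehicle libraries, orange symbols VUF11207 libraries, and vertical ticks group means; the seminal vesicle levels run from -3.08 in VUF11207 replicate 2 to 4.12 in vehicle replicate 2.

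No gene passed the threshold between VUF11207 and vehicle in edgeR's quasi-likelihood test. The 10 named genes with the smallest p had no overlap between the groups because the rule required it, and all were higher with VUF11207. None passed in edgeR, and DESeq2 called 4 of them, Tox3, Scgb2b4-ps, Dcaf12l1 and Apof. Tox3, a chromatin-associated HMG-box protein, averaged 21.1 CPM ± 1.10 (SD, n = 3) with VUF11207 and 6.63 CPM ± 0.995 (SD, n = 3) with vehicle, a log2 fold change of 1.67 ± 0.21 (SE). Apof, apolipoprotein F and a member of the androgen-regulated prostate secretory list, averaged 147 CPM ± 38.7 against 53.7 CPM ± 6.55 (SD, n = 3 each), a log2 fold change of 1.45 ± 0.25 (SE). The interferon-induced genes Ifi27 and Irf7, the latter a transcription factor of the type I interferon response, had log2 fold changes of 0.95 ± 0.23 and 0.86 ± 0.21 (SE).

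The other genes named in this way were Dcaf12l1 (log2 fold change 2.65 ± 0.50, SE), the pseudogene Scgb2b4-ps (3.07 ± 0.60), Fam171b (1.90 ± 0.47), Fchsd2 (0.94 ± 0.24), Cfd (1.34 ± 0.35) and Rgs2 (1.07 ± 0.28). Cfd encodes complement factor D and Rgs2 a regulator of G protein signalling. In mm10, Tox3 lies on chromosome 8 from 90247040 to 90348343, Apof on chromosome 10 from 128268671 to 128270153, Ifi27 on chromosome 12 from 103434211 to 103440239 and Irf7 on chromosome 7 from 141262706 to 141266481. Dcaf12l1 lies on chromosome X from 44786570 to 44790197, and Scgb2b4-ps, annotated as an unprocessed pseudogene, on chromosome 7 from 31401034 to 31403176. Reads of Scgb2b4-ps can be shared with near-identical genes of its family, so its value is uncertain.

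The rule for these names required an average log2 CPM of at least 1, which left out S100a8, a calcium-binding protein of neutrophils. S100a8, chosen after its values were seen, was lower in every VUF11207 library, with a log2 fold change of -3.005 ± 0.69 (SE) and an unadjusted edgeR p of 0.00358, smaller than that of Ifi27 at 0.00488. Its level was low in both groups, at 2.74 CPM ± 1.47 with vehicle and 0.337 CPM ± 0.120 with VUF11207 (SD, n = 3 each).

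**Figure D2:**
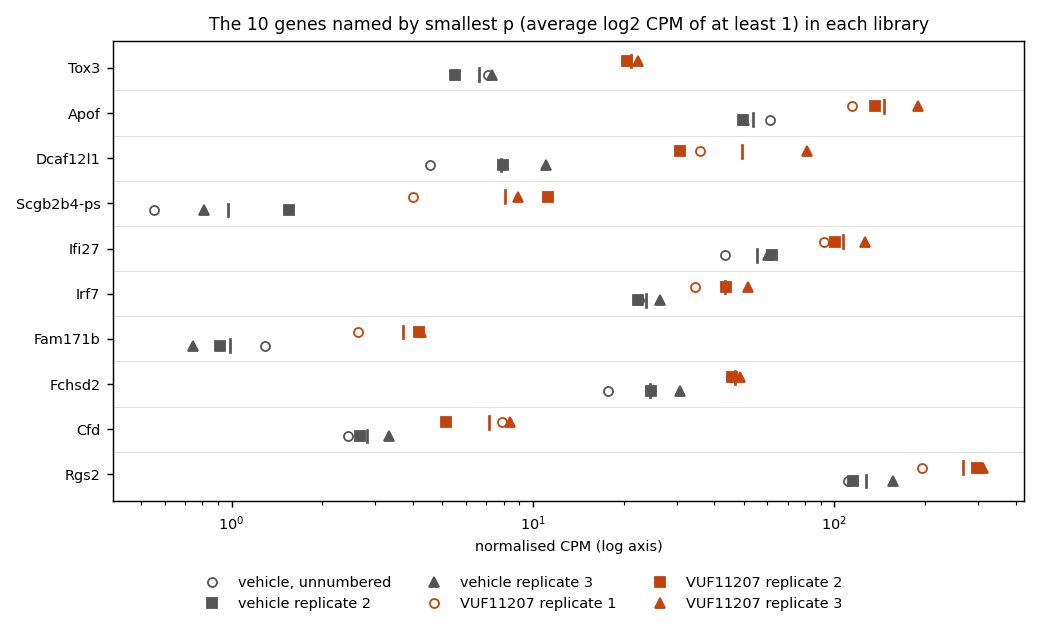
Normalised CPM (log axis) in each library of the 10 genes with the smallest p among those with an average log2 CPM of at least 1 and no overlap between the groups. Grey symbols are vehicle libraries, orange symbols VUF11207 libraries, and vertical ticks group means; the groups do not overlap because the genes were chosen so, none passed the threshold in edgeR, and DESeq2 called Tox3, Scgb2b4-ps, Dcaf12l1 and Apof.

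Of 13753 genes tested with edgeR's quasi-likelihood test, 0 were higher and 0 lower with VUF11207 at a Benjamini-Hochberg adjusted p under 0.05. At an unadjusted edgeR p under 0.05 there were 196 genes, 131 higher and 65 lower. Evenly spread p-values without any difference would give 688. Other groupings of these 6 libraries gave from 24 to 2133 such genes, so 688 is no firm expectation here. The groups did not overlap for 419 genes higher and 347 lower, together 5.57% of the genes tested. Chance gives 10% on average with 3 libraries against 3. The biological coefficient of variation between libraries of a group was 51.4%. In simulated data with the dispersion of these libraries, the test recovered 2.80% of genes changed 2-fold, 43.2% of those changed 4-fold and 82.4% of those changed 8-fold. Simulated genes varied independently of each other, so recovery in these libraries may be lower. DESeq2 called 4 genes higher and 0 lower, with 337 genes at an unadjusted p under 0.05. Its calls were Tox3 (adjusted p 1.17e-06), Scgb2b4-ps (0.00259), Dcaf12l1 (0.00281) and Apof (0.00555), and limma voom called 0.

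The receptor gene Ackr3 and the genes of its ligand and of fibrosis named in advance did not differ between the groups by more than the spread between libraries. Ackr3, on chromosome 1 from 90203980 to 90216751 in mm10, was at 11.2, 4.65 and 5.56 CPM in the unnumbered vehicle library and vehicle replicates 2 and 3, and at 5.58, 12.7 and 10.3 CPM in VUF11207 replicates 1, 2 and 3. Its log2 fold change was 0.41 ± 0.46 (SE), and 0.15 without VUF11207 replicate 2 or 0.90 without the unnumbered vehicle library. Cxcl12, which encodes the chemokine ligand shared by CXCR7 and CXCR4, had a log2 fold change of -0.28 ± 0.26, and Cxcr4 one of -0.31 ± 0.68 (SE). Tgfb1, the profibrotic cytokine TGF-beta 1, was at -0.13 ± 0.41 (SE). Without vehicle replicate 3 the values of Cxcr4 and Tgfb1 turned to 0.0806 and 0.0663, without VUF11207 replicate 2 that of Tgfb1 to 0.13, and without VUF11207 replicate 3 that of Cxcr4 to 0.00746. Cxcl12 was at -0.0421 without vehicle replicate 2.

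Among matrix and myofibroblast genes, the log2 fold changes were 0.71 ± 0.41 (SE) for Col1a1 and 0.22 ± 0.40 for Col3a1, which encode fibrillar collagen chains, 0.64 ± 0.83 for Fn1, which encodes fibronectin, and 0.45 ± 0.69 for Acta2, which encodes smooth muscle actin. Without VUF11207 replicate 2 the values of Fn1 and Acta2 turned to -0.56 and -0.20, and that of Col3a1 to -0.04, and Col1a1 was at 0.26. Without vehicle replicate 2 Col3a1 was at -0.0486. Ptgs2, which encodes the inducible cyclooxygenase, had 4.77, 487 and 359 CPM in the vehicle libraries and 445, 3.46 and 84.5 CPM in VUF11207 replicates 1, 2 and 3, a log2 fold change of -0.67 ± 1.74 (SE). With 1 library left out, the fold change of Ptgs2 ran from -2.67 without VUF11207 replicate 1 to -0.0308 without vehicle replicate 2. The cytokine genes Il1b, Il6 and Tnf fell under the low count filter. Il1b had 35, 8 and 8 counts in the vehicle libraries and 2, 4 and 11 counts with VUF11207, Tnf had 12, 1 and 21 against 6, 2 and 6, and Il6 had 1 count in VUF11207 replicate 2 and 0 elsewhere. In the edgeR fit without that filter, Il1b was at -1.83 ± 1.06 and Tnf at -1.32 ± 1.09 (log2 fold change, SE), neither past the threshold, with 95% intervals from -4.28 to 0.61 and from -3.86 to 1.21.

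**Figure D3:**
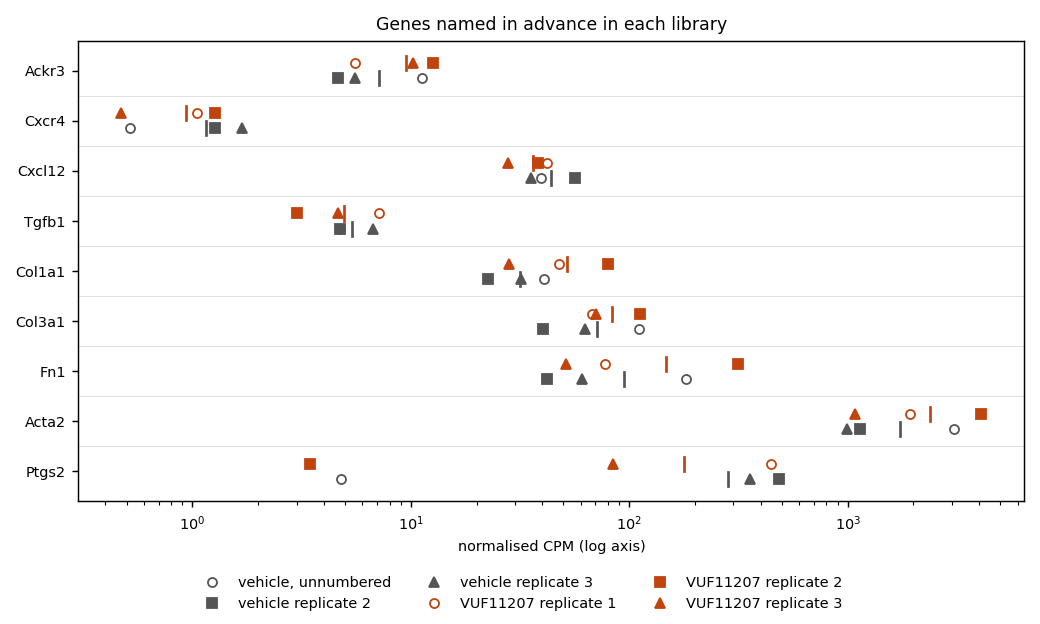
Normalised CPM (log axis) in each library of the tested genes that were named before the data were examined. Grey symbols are vehicle libraries, orange symbols VUF11207 libraries, and vertical ticks group means; the groups overlap for each gene shown, and Ptgs2 spans 3.46 to 487 CPM.

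Gene lists were compared by the mean test statistic of their members against that of all other genes. With the preset inter-gene correlation 12 of 47 lists passed, 6 toward higher and 6 toward lower values with VUF11207. None of the 12 passed with an estimated correlation, and fry called 0 lists. Interferon-induced genes, which act in antiviral defence, leaned toward higher values, with 31 of 33 members positive and a median log2 fold change of 0.51. Their camera adjusted p was 9.47e-11 with the preset correlation and the adjusted p was 0.590 with an estimated correlation. Oas1a was at 1.24 ± 0.38 and Ifit1 at 1.41 ± 0.52 (log2 fold change, SE), Ifit1 being at 0.71 without VUF11207 replicate 3, and the list's level was -0.32, -0.44 and -0.17 in the vehicle libraries against -0.15, 0.53 and 0.54 with VUF11207. Over the 33 genes tested, 0 passed when adjusted over the list alone, as over all genes.

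Cholesterol and fatty acid synthesis genes had 20 of 24 members positive, a median log2 fold change of 0.33 and a camera adjusted p of 4.30e-07, against an adjusted p of 0.590 with an estimated correlation. Within that list Mvd, a mevalonate pathway enzyme, was at 0.74 ± 0.25 and Scd1, a fatty acid desaturase, at 0.99 ± 0.34 (log2 fold change, SE). The cell cycle list had 36 of 40 members positive, a median of 0.39 and a camera adjusted p of 4.55e-08, against an adjusted p of 0.893 with an estimated correlation. Its members Nusap1, Top2a and Ccna2, which act in mitosis and DNA replication, were at 1.39 ± 0.57, 0.72 ± 0.33 and 1.04 ± 0.49. The level of the cell cycle list was 0.41 and 0.61 in VUF11207 replicates 1 and 2 but -0.33 in VUF11207 replicate 3, below vehicle replicates 2 (-0.24) and 3 (0.000535) and above the unnumbered vehicle library (-0.44). In both lists 0 genes passed when adjusted over the list alone.

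The androgen-regulated prostate secretory list was split, with 15 of 28 members positive and a median log2 fold change of 0.28. Its camera adjusted p was 5.22e-06 with the preset correlation and the adjusted p was 0.590 with an estimated correlation. Defb50, a beta-defensin, was at 2.39 ± 0.70 and Wfdc3, a whey acidic protein family member, at 2.81 ± 0.94, while 9530003J23Rik was at -2.98 ± 2.04 and Ceacam10 at -2.82 ± 2.66 (log2 fold change, SE). Wfdc3 was at 1.86 without VUF11207 replicate 3. Without vehicle replicate 2 the value of 9530003J23Rik turned to 1.74 and that of Ceacam10 to 4.41. These 2 genes were at 21040 and 27220 CPM in vehicle replicate 2 and at 2427 and 3590 in VUF11207 replicate 1. Those are the 2 libraries with most seminal vesicle counts, and elsewhere the genes were at most at 320 and 265 CPM. Their negative values thus cannot be read as a fall of prostate secretory genes. When adjusted over the list alone, 1 gene passed, and it was Apof. This list took 6.30%, 6.85% and 12.997% of counts in the vehicle libraries and 11.7%, 16.3% and 29.2% in VUF11207 replicates 1, 2 and 3. Seminal vesicle genes took 64.4% of the counts of vehicle replicate 2 and 28.4% of those of VUF11207 replicate 1, which lowers all other shares there. Sbp alone held 16.3% of the counts of VUF11207 replicate 3. A rise of the list with treatment thus cannot be read from these shares.

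Fibrillar collagens and collagen processing genes had 23 of 30 members positive and a median log2 fold change of 0.21, with a camera adjusted p of 0.0226 and an adjusted p of 0.893 with an estimated correlation. Plod2, a collagen lysyl hydroxylase, was at 1.04 ± 0.45 and Dcn, the proteoglycan decorin, at 0.48 ± 0.30 (log2 fold change, SE), Plod2 being at 0.61 without VUF11207 replicate 3 and Dcn at 0.26 without vehicle replicate 2. Smooth muscle and myofibroblast genes had 22 of 22 members positive, a median of 0.41 and a camera adjusted p of 0.0378, against an adjusted p of 0.893 with an estimated correlation. Hspb6, Pln and Kcnmb1 of that list were at 0.75 ± 0.55, 0.88 ± 0.69 and 0.80 ± 0.64, and at 0.35, 0.14 and 0.26 without VUF11207 replicate 2. The smooth muscle level was 0.71 in the unnumbered vehicle library and 1.17 in VUF11207 replicate 2, the libraries with the highest T cell levels, and -1.001 in VUF11207 replicate 3. Without VUF11207 replicate 2 the camera adjusted p was 0.9748 for the collagens and 0.534 for smooth muscle, and both lists turned to the lower direction. The call was also lost without vehicle replicate 2 (0.759 for the collagens, 0.603 for smooth muscle), vehicle replicate 3 (0.301 and 0.606) and, for smooth muscle, VUF11207 replicate 1 (0.391).

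Red blood cell genes, markers of blood in the specimen, had 0 of 7 members positive and a median log2 fold change of -1.71, with a camera adjusted p of 0.000205 and an adjusted p of 0.893 with an estimated correlation. Alas2, the erythroid enzyme of heme synthesis, was at -1.46 ± 0.56, and Hba-a2 and Hbb-bs, which encode globin chains, at -3.58 ± 1.44 and -2.33 ± 1.15 (log2 fold change, SE). The level of this list was 2.34, -1.02 and 1.26 in the vehicle libraries and -1.37, 0.76 and -1.97 in VUF11207 replicates 1, 2 and 3. Without the unnumbered vehicle library Hba-a2 was at -1.08 and Hbb-bs at -1.09. Without vehicle replicate 3 the camera adjusted p was 0.0591. The globin genes are close copies of each other, and reads shared between them make single values uncertain.

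Macrophage and monocyte markers had 2 of 24 members positive and a median log2 fold change of -0.46, with a camera adjusted p of 0.00106 and an adjusted p of 0.893 with an estimated correlation. Ms4a7 was at -0.74 ± 0.41, Ms4a6c at -1.07 ± 0.66 and Tyrobp, a signalling adaptor of myeloid cells, at -0.91 ± 0.60 (log2 fold change, SE). Without the unnumbered vehicle library Tyrobp was at -0.0615 and Ms4a6c at -0.47. The call was lost without the unnumbered vehicle library (adjusted p 0.311), vehicle replicate 3 (0.0521), VUF11207 replicate 1 (0.119) or VUF11207 replicate 3 (0.0795). Endothelial markers had 3 of 18 members positive, a median of -0.43 and a camera adjusted p of 0.0225, against an adjusted p of 0.893 with an estimated correlation. Flt1, Pecam1 and Ptprb were at -0.70 ± 0.43, -0.55 ± 0.36 and -0.97 ± 0.65. Ptprb was at 0.0256 without the unnumbered vehicle library, and Flt1 and Pecam1 were at -0.44 and -0.34 without VUF11207 replicate 2. The endothelial call was lost without the unnumbered vehicle library (adjusted p 0.698), vehicle replicate 2 (0.0856) or VUF11207 replicate 2 (0.506).

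MAPK feedback and immediate early genes had 5 of 30 members positive, a median log2 fold change of -0.22 and a camera adjusted p of 0.00131, against an adjusted p of 0.893 with an estimated correlation. Ier3, Dusp1 and Klf2 were at -0.57 ± 0.24, -0.45 ± 0.23 and -0.67 ± 0.34 (log2 fold change, SE), and Klf2 was at -0.30 without vehicle replicate 2. The unfolded protein response list had 2 of 28 members positive and a median of -0.22, with Ern1, a sensor of stress in the endoplasmic reticulum, at -0.51 ± 0.25, or -0.29 without vehicle replicate 2. Cytosolic ribosomal proteins had 1 of 45 members positive and a median of -0.21, with Rps2 at -0.39 ± 0.38, or -0.14 without vehicle replicate 2. Each of these 2 lists had a camera adjusted p of 0.0225 and an adjusted p of 0.893 with an estimated correlation. The MAPK call was lost without vehicle replicate 2 (adjusted p 0.0634), vehicle replicate 3 (0.0823) or VUF11207 replicate 3 (0.172). For the unfolded protein response the adjusted p was 0.476 without vehicle replicate 2, 0.307 without the unnumbered vehicle library and 0.229 without VUF11207 replicate 1, and for the ribosomal proteins 0.361, 0.484 and 0.693, the direction of the ribosomal list turning to higher without the unnumbered vehicle library or VUF11207 replicate 1. Red blood cell, macrophage, endothelial, MAPK, unfolded protein response, ribosomal, collagen and smooth muscle lists each had 0 genes when adjusted over the list alone.

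**Figure D4:**
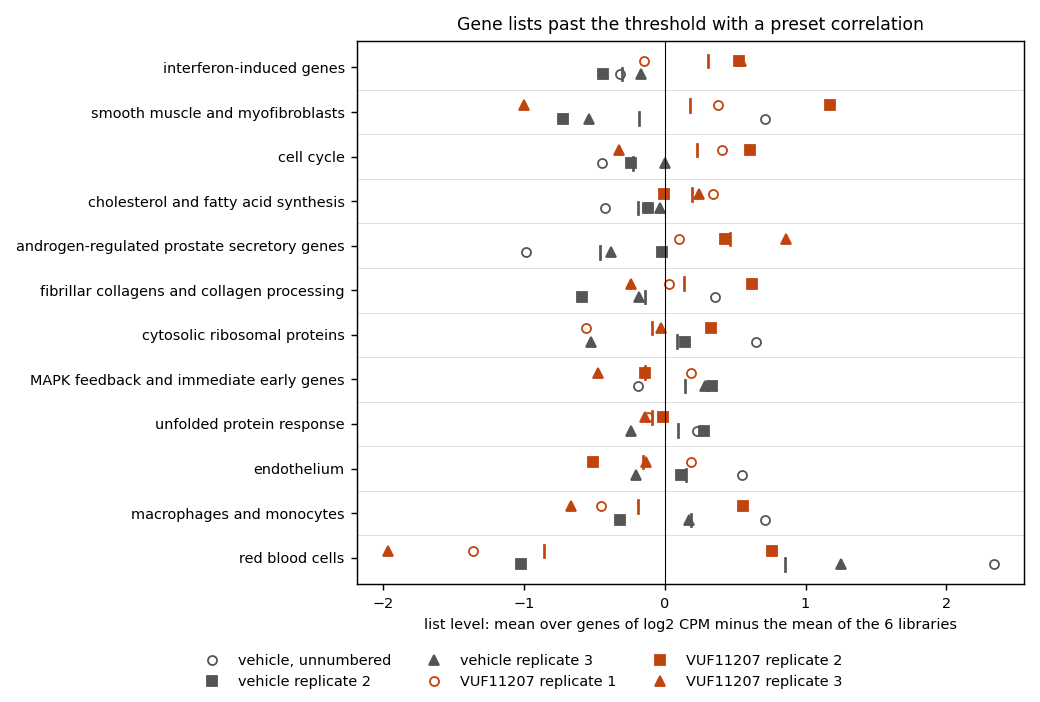
Levels in each library of the 12 gene lists past the threshold with the preset correlation, on a log2 scale (x axis: mean over genes of log2 CPM minus the mean of the 6 libraries). Grey symbols are vehicle libraries, orange symbols VUF11207 libraries, and vertical ticks group means; the interferon levels are -0.15 or higher with VUF11207 and -0.17 or lower with vehicle, and the groups overlap for red blood cells.

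The lists of fibrosis and inflammation did not pass otherwise. Matrix glycoproteins of fibrosis had 15 of 28 members positive (camera adjusted p 0.255), and TGF-beta ligands, receptors and targets had 5 of 25 (0.131). Proinflammatory cytokines had 1 of 8 members positive (0.112), inflammatory chemokines 8 of 23 (0.907) and NF-kB targets 3 of 21 (0.1399). T cell markers had 4 of 17 members positive (0.131), B cell markers 7 of 10 (0.997) and luminal epithelium markers 10 of 20 (0.997). The chemokine receptor axis of the compound had 7 of 15 members positive (0.441). Neutrophil markers had 3 of 7 members positive and a median log2 fold change of -0.62 (0.0643), and when adjusted over the list alone 1 gene passed, S100a8. Median, mean and test differed in sign for lists that did not pass: glucocorticoid-induced genes, NRF2 and oxidative stress genes, oxidative phosphorylation, epididymis and vas deferens, peripheral nerve and glia, adipose tissue and plasma cells.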

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

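The alternatives that leave out the 2 libraries with most seminal vesicle counts or the 50 most abundant genes, and those with a covariate, were chosen after seeing the data; the others were planned. The count of genes higher with VUF11207 was 0 with edgeR under each other alternative, but 4 with DESeq2 and 3 with library totals only (Scgb2b12, Scgb2b7 and Wfdc3, adjusted p 0.0323); genes lower were 0 under each alternative. The count of gene lists that passed, 12, fell to 0 with an estimated correlation and to 0 with fry. It ran from 8 to 22 when 1 library was left out, with 22 without VUF11207 replicate 2. The estimated correlation takes the lists' own correlation into account; other causes were not tested.

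With a replicate block there were 0 genes higher, 0 lower and 13 lists. Deviations from the group mean correlated across genes at -0.593, -0.332 and 0.0525 between same-numbered libraries. They gave no sign of pairing, but so few pairs cannot exclude it. The unnumbered vehicle library, given the remaining number 1, correlated best with VUF11207 replicate 2.

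Log2 fold changes that changed sign, none past the threshold, were those of Ceacam10 (1.75 with the replicate block, 1.20 without the 2 libraries with most seminal vesicle counts), Cxcl12 (0.0235 with library totals only) and Rpl15 (0.01045 with library totals only, 0.0352 without those 2 libraries). With 1 library left out, ranges were -5.57 to 1.74 for 9530003J23Rik, -6.03 to 4.41 for Ceacam10, -0.20 to 1.16 for Acta2, -0.0486 to 0.70 for Col3a1, -0.66 to 0.0806 for Cxcr4, -0.56 to 1.52 for Fn1, -1.38 to 0.0256 for Ptprb and -0.47 to 0.13 for Tgfb1. Adjusted p of lists that changed direction ranged from 6.18e-06 to 0.9748 for fibrillar collagens, 7.07e-09 to 0.693 for cytosolic ribosomal proteins (0.197 without those 2 libraries) and 1.57e-14 to 0.606 for smooth muscle. Interferon, androgen-regulated, cell cycle and cholesterol lists passed in 6 of 6 such fits with the preset correlation, and none of them passed with an estimated one. The cause was not tested. Other pseudocounts and filters, meant for normalized values, did not apply to counts. The spread between libraries, more than the depth, limited the calls: the biological coefficient of variation was 51.4%.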

Other observations

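Each test of an explanation below was chosen after the result was seen, except the splits of the libraries for gene lists. Genes of the androgen-binding protein family (Scgb1b and Scgb2b), secretoglobins found in mouse saliva and other secretions, were also chosen after their values were seen. All 12 measured members had positive log2 fold changes, with a median of 2.48, and 8 had an unadjusted p under 0.05 in edgeR. In that fit 0 passed the threshold over all genes. DESeq2 called Scgb2b4-ps (adjusted p 0.00259), and edgeR with library totals only called Scgb2b12 and Scgb2b7 (adjusted p 0.0323). They lie on chromosome 7 between 31401034 and 34022881 in mm10, and reads shared between these close copies make them uncertain and not independent of each other. Scgb2b7 was at 27.2, 149 and 61.7 CPM in the vehicle libraries and at 248, 604 and 637 CPM in VUF11207 replicates 1, 2 and 3.

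Ptgs2 was named in advance as an inflammatory gene, and Akr1b7, an aldo-keto reductase, is a member of the epididymis and vas deferens list. Both were low in the unnumbered vehicle library and VUF11207 replicate 2, and their relation was not tested. Akr1b7 and S100a9 were chosen after their values were seen. Akr1b7 was at 28.0, 5639 and 3134 CPM in the unnumbered vehicle library and vehicle replicates 2 and 3, and at 7148, 41.5 and 1149 CPM in VUF11207 replicates 1, 2 and 3. In the same order Ptgs2 was at 4.77, 487, 359, 445, 3.46 and 84.5 CPM. The levels of the epididymis and vas deferens list, which includes Akr1b7, were -2.46, 1.36, 0.88, 1.38, -1.40 and 0.25 in that order. Whether Ptgs2 reflects inflammation or such tissue in the specimens was not tested. S100a9, the partner of S100a8 in neutrophils, had a log2 fold change of -3.56 ± 1.16 (SE) and was lower in each VUF11207 library, not past the threshold.

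That no gene passed in edgeR (196 genes at an unadjusted p under 0.05, 4 calls by DESeq2) may reflect different pieces of tissue in the specimens. The spread within groups of 6 of 6 lists of other tissues (seminal vesicle, skeletal muscle, epididymis and vas deferens, urothelium, adipose tissue, red blood cells) lay above the 95th percentile of 10000 random lists matched on expression. Genes of such lists also move together for other reasons, and using the seminal vesicle level or the first principal component as a covariate still gave 0 genes. Whether a few genes taking most of the counts were the cause was not decided. The biological coefficient of variation was 50.7% without the 50 most abundant genes and 51.4% with them. It is shared by all genes tested, and TMM had already adjusted for such genes, so leaving them out could hardly move it. The TMM factors ran from 0.425 to 1.33 with these genes and from 0.936 to 1.06 without them. The 10 splits of the 6 libraries test nothing here, since each of the 10 reaches a real count of 0 genes whatever the data (the highest other was 3). The splits that put the unnumbered vehicle library with VUF11207 replicate 2 gave 827 to 2133 genes at an unadjusted p under 0.05, which points to a structure of the samples other than treatment.

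The 12 list calls could come from members of a list moving together from library to library: 0 calls held with an estimated correlation. Of the 10 splits, 5 gave at least 12 lists, the real split being 1 of them. The splits above it, with 14 to 19 lists, each put the unnumbered vehicle library with VUF11207 replicate 2. The remaining splits gave 4 to 9 lists. A count of 12 lists was thus within what groupings other than treatment gave. With 10 splits a share under 0.05 could not be reached. A response to VUF11207 stays open for these lists, untested beyond this comparison.

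The interferon-induced list was higher with VUF11207 by 0.61 on the log2 scale, with a 95% interval from -0.05 to 1.28. More leukocytes in the VUF11207 specimens cannot be told apart from a change within cells: leukocyte lists together differed by -0.28, but the upper bound of their difference was 1.16, above the interferon difference. With the first principal component as a covariate, 105% ± 43.2 (SE) of the interferon change was left, so tissue content along that component cannot be told apart either, because 6 libraries leave that error. An effect of VUF11207 on interferon-induced genes is a hypothesis that these data leave open.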
